A study of Mus musculus and Homo sapiens with 8 samples.

How the data were processed

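RNA was measured in 8 samples. A mixture of 3 human cell lines was profiled as 1 single-cell library and 1 bulk library. Mammary glands of 2 female FVB/NJ mice aged 12 weeks, numbered 3 and 4, were profiled as 2 single-cell libraries, 2 bulk libraries of pooled cell suspension and 2 bulk libraries of fresh-frozen gland. Per the labels' protocols, glands were digested overnight in collagenase and hyaluronidase, single-cell libraries were made with the 10x Genomics 3 prime v2 kit, and bulk libraries were made from total RNA with an Illumina TruSeq mRNA kit.

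The deposited single-cell matrices held UMI counts per gene and barcode as whole numbers, and the submitters' processing notes list Cell Ranger. The deposited bulk tables held estimated counts per gene symbol, partly fractional, and the submitters' processing notes list STAR, SAMtools, Picard and Salmon with the builds mm10, hg19 and GRCh38. The role of each tool, the tool versions and the build used for each file are not given in the sources used here. A second deposited bulk table held a normalized signal, which equalled the authors' estimated counts times 1 factor per library that set the upper quartile of genes above 0 to 1000, as checked on the values. The mouse bulk table had 47480 entries, of which 27 carried a bare number in place of a gene name; these 27 held 0.173% to 0.179% of the counts of each library and were left out, which left 47453 genes. The human bulk table had 58387 entries, of which 28 with 0.205% of the counts were left out for the same reason. Genomic positions came from GENCODE vM21 on GRCm38. Human positions were not used here. XIST and Y-linked genes were left out of every human table.

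Bulk estimated counts were rounded to whole numbers for the tests. Suspension was compared with fresh-frozen gland with edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM normalization, robust dispersion estimates and the quasi-likelihood F-test on group alone, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Of the genes in the table, 18405 passed the filter, and the common biological coefficient of variation was 0.115. The 27 mouse gene lists (17 of cell types, 10 of cell states) were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and also with an estimated correlation. Camera asks whether a list changed more than the other genes, and fry, run beside it, asks whether a list changed at all, so the calls of the 2 tests answer different questions. Log2 fold changes are suspension relative to fresh-frozen. A gene with 1 to 3 counts in 1 group was given its count ratio with an exact counting interval beside the fitted value.

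The same number marks the same mouse in the labels, so the numbers pair the samples. The correlation across genes of same-mouse deviations from the group means was 0.085. The fit without the mouse term was the main one, and the fit with mouse as a replicate block was an alternative. Libraries of 1 group varied more than counting error allows, with a chi-square per degree of freedom of 26.4 between the fresh-frozen pair and 35.8 between the suspension pair.

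Single-cell matrices were analysed with scanpy 1.11.5 in Python 3.11.15. Human barcodes were kept with at least 1000 UMIs, 500 genes and at most 20% mitochondrial UMIs, and mouse barcodes with at least 500 UMIs, 250 genes and the same mitochondrial limit. Doublets called by Scrublet were removed, with the caveat that only 0.299% of human and 0.140% of mouse 3 cells were called. Cells were clustered with leidenalg 0.10.2 at a resolution of 0.5 on 15 neighbours, 20 principal components and 2000 variable genes. Each cluster was named by the marker list with the highest scaled score, where the score was at least 0.6, led the next class by at least 0.1 and had at least 3 detected markers. Classes, not lists, were compared for the lead, and where the pan-luminal list led, the cluster took the name of the luminal subtype list with the higher score. A marker entered where some cluster reached 100 CPM, and a cluster needed 10% haemoglobin UMIs to be called erythroid. These naming thresholds were set after the clusters had been seen. Shares of cells carry exact (Clopper-Pearson) binomial 95% intervals, which cover counting error only.

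Shares in bulk were estimated with weighted non-negative least squares (W-NNLS), written here after the published weighting idea and not with the authors' software. Class profiles were mean relative abundances times mean UMIs per cell, over 32957 human or 27826 mouse genes present in both tables. The shared genes held 97.7% of the human bulk counts and 91.1% to 97.4% of the mouse bulk counts. Weights were the inverse of a constant of 0.0001 plus the squared residual and the variance across cells, with up to 1000 iterations. Intervals span the central 95% of 200 resamples of genes. Differences between the mouse groups were put to a two-sided exact permutation test, for which 2 libraries against 2 allow no p below 0.333. For the comparison of summed single cells with bulk, log2 ratios of CPM were taken for genes at 50 CPM or more in at least 1 library, with 3 counts as the floor, and each list's median was placed among 10000 random lists matched over 20 expression bins. A list outside the central 95% of the random lists was called.

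Gene lists, tests, most alternatives and a rule for naming single genes were fixed before the data were examined. In the test between tissue states, these were the 6 largest rises and 6 largest falls among genes past the threshold with a mean log2 CPM of at least 4 and no overlap between groups, plus up to 3 members with the highest mean of each list, 91 genes in all. In the comparisons of 1 library with 1 library, these were the 6 highest and 6 lowest ratios plus up to 3 members per list. Other list members named as exceptions to their list, other genes named in the assay comparisons and the genes shown for single-cell classes were chosen after their values were seen. Alternatives and tests added later are named as such in the closing section.

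The methods were tested on simulated data. In 18020 simulated genes, edgeR recovered 66 of 97 genes changed by 1 on the log2 scale and 97 of 99 changed by 2, and called 10 unchanged genes. Few genes changed in that simulation, so it did not test the normalization where most genes change, as between the mouse groups. Under counting noise, W-NNLS returned simulated shares with a largest error of 0.0199 points for the human and 0.0541 points for the mouse classes. A random gene-specific factor between assays raised its largest error to 5.50 points in human and 3.68 points in mouse. The simulated bulk was drawn from the same class profiles that were fitted, and the factor was independent between genes. These errors thus do not cover a class missing from the reference or an assay difference tied to gene features such as length. The ratio of summed cells to bulk recovered 200 of 200 simulated 4-fold changes in each species, counted where the ratio passed 2-fold. That simulated bulk was drawn from the single-cell shares with counting noise alone, so it held no difference between assays. In the real libraries 78.7% of human and 73.1% of mouse genes differed at least 2-fold, a case it did not test. Alternatives covered normalization, DESeq2 1.42.0, limma on the normalized table, count filters, the replicate block, each library left out, cell filters, clustering, the naming of cells, weights, gene sets and the reference profiles.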

Results

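The mixture held a line named MDA-MB-438, which is kept here as the labels print it, the breast cancer line MCF7 and human dermal fibroblasts (HF), at stated shares of 60%, 30% and 10%. It was measured in 1 single-cell library and 1 bulk library without replicates. The mouse samples fell into 3 groups of 2 libraries each, namely single cells, bulk cell suspension and bulk fresh-frozen mammary gland. The human single-cell matrix held 3022 barcodes with 58470268 UMIs and a median of 17539.5 UMIs per barcode, and 3002 cells were used. The mouse 3 matrix held 4298 barcodes with 31657040 UMIs and a median of 5931.5 UMIs, and 4292 cells were used. The mouse 4 matrix held 3108 barcodes with 38281 UMIs in all, a median of 9 and a maximum of 250, so that no barcode passed the filter and all mouse single-cell values come from mouse 3. The bulk totals in estimated counts were 42569257 and 69104991 for suspensions 3 and 4, 51312512 and 52993829 for fresh-frozen glands 3 and 4, and 96256037 for the human mixture. The series concerns the estimation of cell type shares in bulk tissue from single-cell profiles.

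The first comparison asked how the transcriptome of the dissociated cell suspension differed from that of the fresh-frozen gland. Genes of fat cells were almost lost from the suspension, genes of lymphocytes and red cells were much lower, and pan-luminal genes, most luminal secretory genes and those of inflammatory, oxidative and early stress responses were higher. Hormone-sensing luminal genes went both ways. At the level of gene lists, none of these differences passed camera with an estimated correlation (lowest adjusted p = 0.120). With 2 libraries per group, that test rests on few residual degrees of freedom and has little power. The adipocyte list, with 10 of 10 members lower, had an unadjusted p of 0.0121 in this camera test. A list that did not pass it is thus not shown to be unchanged. Of 18405 genes tested with edgeR's quasi-likelihood test, 13266 passed after Benjamini-Hochberg adjustment, with 6358 higher and 6908 lower in the suspension (n = 2 libraries per group). At least 2-fold differences were found among these in 3235 genes that were higher and 4648 that were lower. Spearman's rho across genes was 0.996 between the fresh-frozen pair and 0.994 between the suspension pair, against 0.862 to 0.863 between groups, and genes are not independent replicates.

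Among genes with the largest rises, Serpinb2, an inhibitor of plasminogen activators, went from 0.0475 ± 0.0151 to 402 ± 102 CPM (mean ± SD, n = 2), a log2 fold change of 12.99 with a standard error of 0.36. It lies on chromosome 1 from 107511423 to 107535478 on GRCm38. Cxcl5, a chemokine that attracts neutrophils, lies on chromosome 5 from 90759360 to 90761624 and rose by 12.54 on the log2 scale to 1306 ± 207 CPM. Saa3, an acute-phase protein, rose by 11.51 to 1079 ± 154 CPM, and Il6, a cytokine, rose by 11.47 to 328 ± 26.9 CPM. Cxcl3 had 3 counts and Olr1 had 1 count in the fresh-frozen pair, and their log2 count ratios were 12.21 (counting interval 10.66 to 14.49) and 12.03 (9.55 to 17.33). Among the 6 largest falls, Ucp1, the uncoupling protein of brown fat, lies on chromosome 8 from 83290352 to 83298452 and went from 1188 ± 499 to 0.647 ± 0.210 CPM, a log2 fold change of −10.89. Gys2, a glycogen synthase, had a log2 fold change of −11.46, Ces1f of −10.97, Cyp2e1 of −10.86 and Tmem45b of −10.81. Arxes1 had 1 count in the suspension pair, with a log2 count ratio of −12.77 (−18.08 to −10.29). Each of these 12 genes passed edgeR's quasi-likelihood test, with adjusted p from 3.9e-07 to 2.9e-05.

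Members named below as exceptions to their list were chosen after their values were seen. All 13 members of the NF-kB and chemokine list rose, with a median log2 fold change of 7.85. Cxcl1 went from 1.60 ± 0.127 to 1360 ± 286 CPM. The list passed camera with adjusted p = 5.6e-26, and it had adjusted p = 0.120 with an estimated correlation. All 9 members of the matrix protease list rose (median 6.02), among them Mmp3, a stromelysin, from 16.2 ± 3.86 to 4120 ± 394 CPM, Serpine1 at 6.02 and Mmp14 at 2.91. That list had a camera adjusted p = 2.8e-12, and adjusted p = 0.120 with an estimated correlation. All 9 members of the oxidative stress and metallothionein list rose (median 4.16), among them Hmox1, which degrades haem, from 45.8 ± 1.82 to 3143 ± 30.1 CPM, Mt2 at 5.60 and Srxn1 at 4.16. Its camera adjusted p was 1.2e-19, with adjusted p = 0.120 with an estimated correlation. All 13 immediate early genes rose (median 3.29), with Fos at 5.46, Jun at 3.69 and Zfp36 at 2.46. Their camera adjusted p was 5.8e-15, with adjusted p = 0.163 with an estimated correlation.

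All 9 members of the unfolded protein response list rose (median 2.08), among them the endoplasmic reticulum chaperone Hspa5 at 3.23 and the transcription factors Xbp1 at 2.08 and Atf4 at 1.47. The camera adjusted p was 3.7e-06, with adjusted p = 0.163 with an estimated correlation. In the heat shock list, 10 members rose and 1, Dnaja1, did not pass (median 1.82). Hsp90ab1 had a log2 fold change of 1.82 and Hspa8 of 1.16, while the 5.58 of Hspa1b is uncertain because Hspa1a is a nearly identical copy. The camera adjusted p was 3.7e-06, with adjusted p = 0.416 with an estimated correlation. In the hypoxia and glycolysis list, 6 members rose, 4 did not pass and 1 fell (median 1.80). Ndrg1 rose by 3.34, the glycolytic enzymes Ldha and Eno1 stood at 0.36 and 0.10 without passing, and Hk2, a hexokinase, had a log2 fold change of −1.23. Camera gave this list adjusted p = 0.0114, and adjusted p = 0.540 with an estimated correlation. Fry, which asks whether the list changed at all, gave adjusted p = 0.0684.

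Of the epithelial and stromal lists, the pan-luminal, luminal secretory, fibroblast, endothelial and basal/myoepithelial lists were higher in the suspension, with medians of 0.49 to 2.33, and the hormone-sensing and pericyte lists, given further below, had medians under 0 and did not pass. All 7 pan-luminal genes rose (median 2.33), with the keratins Krt18 at 2.33 and Krt8 at 2.16 and the adhesion molecule Epcam at 2.28 (camera adjusted p = 4.1e-07, and adjusted p = 0.163 with an estimated correlation). In the luminal secretory list, 11 genes rose and 4 did not pass (median 1.91). Ltf, which encodes lactoferrin, went from 51.6 ± 16.2 to 2357 ± 575 CPM, Trf rose by 1.91 and Mfge8 by 0.47; Csn2, a milk casein, stood at −1.34 without passing. Camera gave adjusted p = 0.000406, and adjusted p = 0.472 with an estimated correlation. In the fibroblast list, 7 genes rose, 3 did not pass and Dpt fell, with a log2 fold change of −0.69 (median 0.62). Dcn, which encodes decorin, went from 750 ± 52.9 to 3561 ± 172 CPM, while the collagen gene Col3a1 stood at 0.13 without passing. Col1a2, at 0.34, had an edgeR adjusted p of 0.0805, and 0.0443 with mouse as a replicate block. The fibroblast list had a camera adjusted p of 0.00933, with adjusted p = 0.325 with an estimated correlation. In the endothelial list, 9 genes rose, among them Cdh5 at 1.30, Pecam1 at 1.00 and Eng at 0.43, Tie1 did not pass and Kdr fell, with −0.64 (median 0.99). Endothelial genes had a camera adjusted p of 0.0177, with adjusted p = 0.539 with an estimated correlation. In the basal/myoepithelial list, 7 genes rose, among them the contractile genes Myh11 at 0.49 and Acta2 at 0.48. Krt15 and Oxtr fell, with −0.91 and −0.35, and Mylk and Cnn1 did not pass. The list had a median of 0.49 and a camera adjusted p of 0.0400, with adjusted p = 0.540 with an estimated correlation.

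The adipocyte list fell as a whole, with 10 of 10 members lower and a median log2 fold change of −9.58. Car3, a carbonic anhydrase abundant in fat, went from 8575 ± 457 to 10.9 ± 1.88 CPM, Cfd, which encodes adipsin, from 3625.0 ± 289 to 4.34 ± 1.01 CPM, and Pck1 had a log2 fold change of −10.56. Adipocyte genes had a camera adjusted p of 2.0e-42, with adjusted p = 0.120 with an estimated correlation. All 11 genes of lipid synthesis and lipolysis fell (median −4.61). Scd1, a fatty acid desaturase, went from 32475 ± 2272 to 686 ± 75.6 CPM, Fasn, the fatty acid synthase, from 13330.0 ± 879 to 129 ± 12.0 CPM, and Lpl had a log2 fold change of −3.76. Lipid genes had a camera adjusted p of 1.5e-25, with adjusted p = 0.163 with an estimated correlation. In the cholesterol synthesis list, 7 genes fell, among them Insig1 at −4.08, Hmgcs1 at −2.03 and Fdft1 at −1.07, Sqle did not pass, and Hmgcr, the rate-limiting enzyme, rose by 0.36 (median −1.66). Its camera adjusted p was 0.00039, with adjusted p = 0.263 with an estimated correlation.

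**Figure D1:**
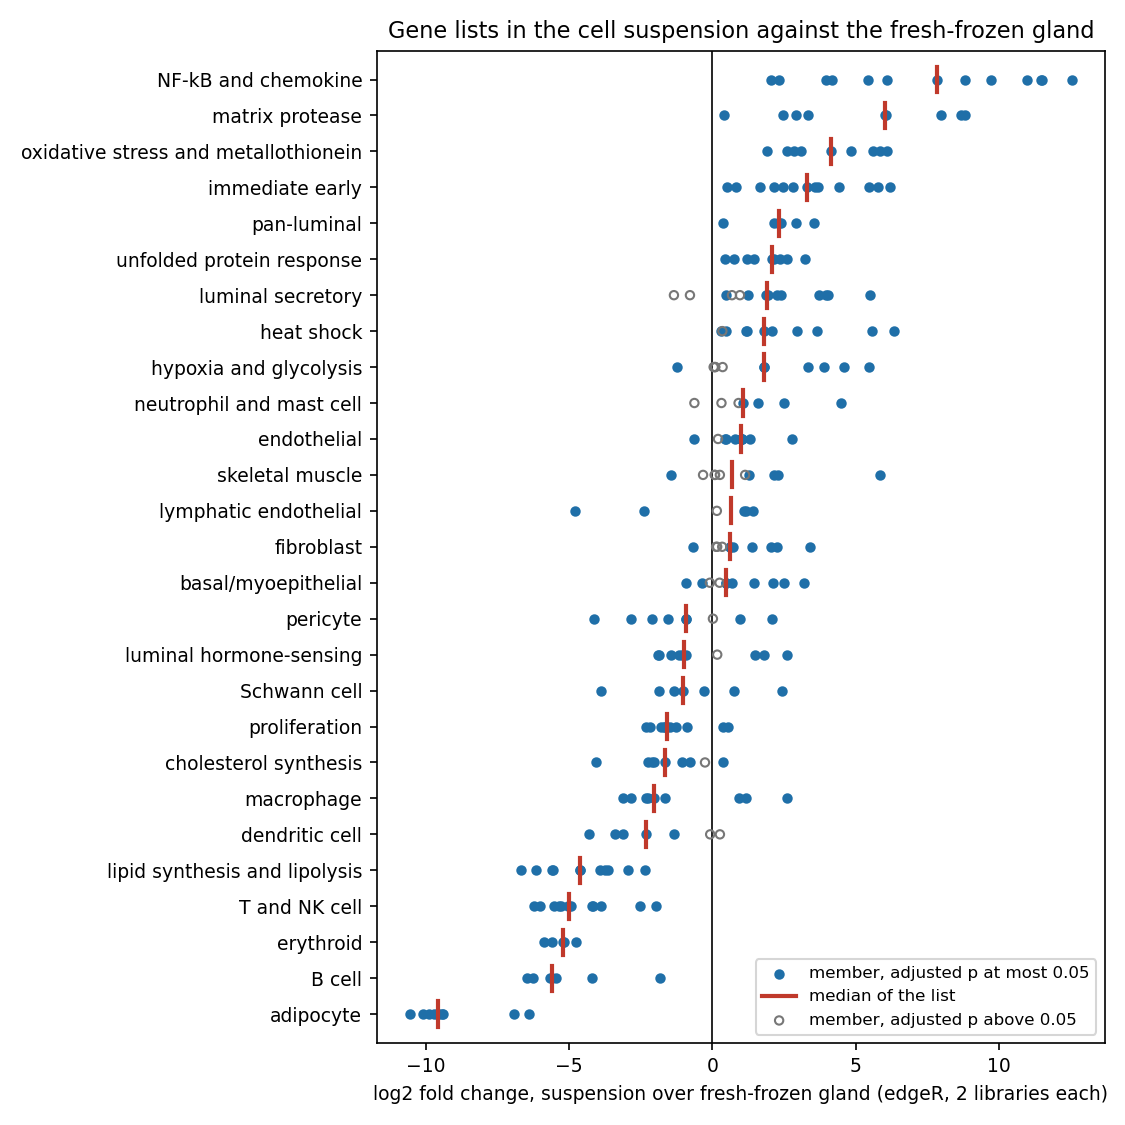
Log2 fold changes of the genes of 27 mouse lists, suspension relative to fresh-frozen gland, with 1 point per tested gene and the list median marked (n = 2 libraries per group). Medians run from −9.58 in the adipocyte list to 7.85 in the NF-kB and chemokine list.

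Lymphocyte and red cell genes fell in every member tested. The 7 B cell genes had a median of −5.60, with Ighd at −6.27, Cd79a, a subunit of the B cell receptor, at −5.66 and Ighm at −4.21. B cell genes had a camera adjusted p of 6.4e-10, with adjusted p = 0.263 with an estimated correlation. The 13 T and NK cell genes had a median of −5.01, with Trbc2 at −5.27, Cd4 at −4.22 and the T cell kinase Lck at −4.15 (camera adjusted p = 5.2e-05, and adjusted p = 0.428 with an estimated correlation). The 5 erythroid genes had a median of −5.21, with the haemoglobin gene Hbb-bs going from 903 ± 277 to 33.6 ± 12.3 CPM. The separate values of Hba-a1 (−5.21) and Hba-a2 (−5.20) are uncertain because the genes are nearly identical copies. The erythroid list had a camera adjusted p of 0.000406, with adjusted p = 0.428 with an estimated correlation. In the macrophage list, 6 genes fell, among them Lyz2 (−2.85), the complement gene C1qa (−2.31) and Csf1r (−2.26), and 3 rose, namely Fcgr1 (2.61), Adgre1 (1.17) and Cd68 (0.92). The list median was −2.05 and the camera adjusted p 0.00474, with adjusted p = 0.472 with an estimated correlation. In the dendritic cell list, 5 genes fell, among them Flt3 (−3.12) and Ccr7 (−2.32), while Zbtb46 (−0.08) and Clec9a (0.26) did not pass (median −2.32). The camera adjusted p was 0.0307, with adjusted p = 0.428 with an estimated correlation; without fresh-frozen library 4 the camera adjusted p was 0.0615.

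The remaining 7 lists did not pass camera. In the proliferation list, 9 genes fell, among them Mki67 at −2.19 and Mcm5 at −1.49, and Pcna and Tyms rose by 0.39 and 0.54 (median −1.57, camera adjusted p = 0.0727). In the hormone-sensing luminal list, Ly6a (2.61), Prom1 (1.80) and Pgr (1.48) rose, 6 genes fell, including the oestrogen receptor gene Esr1 at −1.06, and Prlr stood at 0.17 without passing. Its median was −0.998 and its mean −0.23, while the camera test pointed upward (adjusted p = 0.574). Ly6a had 73776 UMIs over all cells of mouse 3 but was not among the leading genes of the hormone-sensing cluster. The rise of Ly6a thus cannot be assigned to hormone-sensing cells. In the pericyte list, Ndufa4l2 (2.09) and Pdgfrb (0.98) rose, 6 genes fell, including Rgs5 at −0.91, and Notch3 stood at 0.02 without passing (median −0.92, adjusted p = 0.111). In the Schwann cell list, Sox10 (2.43) and Plp1 (0.74) rose and S100b (−3.88), Mpz (−1.85), Cnp (−1.33), Pmp22 (−1.02) and Mbp (−0.30) fell (median −1.02, adjusted p = 0.220). In the neutrophil and mast cell list, S100a8 (4.48), Csf3r (2.49), Cma1 (1.58) and Mcpt4 (1.06) rose and 3 did not pass (median 1.06). This list had a camera adjusted p of 0.0560, and 0.0432 with mouse as a replicate block. Its member Cpa3, at 0.32, had an edgeR adjusted p of 0.127, and 0.0411 with the block. In the skeletal muscle list, Ckm (5.84), Tnnc2 (2.29), Atp2a1 (2.14) and Tnnt3 (1.28) rose, Myh1 (−1.43) fell and 5 did not pass (median 0.70, adjusted p = 0.297). Among these, Acta1, at 1.14, had an edgeR adjusted p of 0.0951, and 0.0013 with the block. In the lymphatic endothelial list, Reln (1.41), Prox1 (1.16) and Flt4 (1.12) rose, Ccl21a (−4.80) and Lyve1 (−2.39) fell and Mmrn1 did not pass. That list had a median of 0.64 but a mean of −0.56, and camera pointed upward (adjusted p = 0.887), and Lyve1 had an edgeR adjusted p of 0.00866, and 0.0845 with the block.

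With p-values adjusted over the list alone, 26 of 27 lists had the same count of changed members as over all genes, and the cholesterol list had 9 in place of 8. Camera with its preset correlation called 12 lists higher and 8 lower, and no list passed with an estimated correlation, where the lowest adjusted p was 0.120, while fry, which asks a different question, called 23. The median log2 fold change of all genes was −0.04, against −0.14 with upper-quartile normalization and −0.13 with limma on the normalized table, so small fold changes hold relative to that shift. The calls of Acta2, Mfge8, Rgs5, Mbp and Lyve1 were each lost when 1 of the 4 libraries was left out. The suspension libraries also carried a different mix of cell types, and the fold changes were not separated into mix and response.

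In the single-cell mixture, the question was whether the shares of the 3 lines could be read from cells mixed at a stated ratio. MDA-MB-438 made up 1974 of 3002 cells, 65.8% (95% interval 64.0 to 67.5), MCF7 682 cells, 22.7% (21.2 to 24.3), and HF 346 cells, 11.5% (10.4 to 12.7). The stated 60% for MDA-MB-438 and 30% for MCF7 lay outside these intervals, which cover counting error only. The stated 10% for HF lay just outside, but inside the interval at a clustering resolution of 1.5, where HF was 319 cells, 10.6% (9.55 to 11.8), and in 4 other alternatives. At that resolution MDA-MB-438 and MCF7 kept 1974 and 682 cells, and 27 cells were left unnamed. The lower HF share there thus came with cells that lost their name. The clusters differed in the genes that named them. TFF1, a trefoil peptide of oestrogen-responsive cells, stood at 6372 CPM in MCF7, against 64.0 in MDA-MB-438 and 86.3 in HF. COL1A2, a fibrillar collagen gene, stood at 1418 CPM in HF, against 5.08 in MCF7 and 4.95 in MDA-MB-438. EGFR, a growth factor receptor, stood at 469 CPM in MDA-MB-438, against 89.2 in HF and 14.4 in MCF7, and S100A9 at 3638 CPM, against 368 and 80.7. COL1A2 UMIs were seen in 100% of HF cells and in 9.82% of MCF7 cells, at median depths of 10425.5 and 19014.5 UMIs, so a UMI of it in a cell of another line was read as background. Genes of 2 lines were found together in 42 of 3011 cells before doublets were removed.

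In the bulk mixture, W-NNLS on these single-cell profiles gave 11.6% for MDA-MB-438 (gene resampling interval 4.89 to 31.8), 24.0% for MCF7 (0 to 38.7) and 64.4% for HF (53.3 to 76.6). The order of the lines was thus opposite to the stated one, and the stated shares of MDA-MB-438 and HF lay outside the intervals. The values depended on the weights and genes used: without weights the shares were 72.1%, 27.9% and 0%, and with the 50 leading genes of each line 24.6%, 55.6% and 19.8%. Other weight constants gave MDA-MB-438 shares from 5.88% to 90.3%. The correlation across genes between fitted and measured log2 levels was 0.816.

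**Figure D2:**
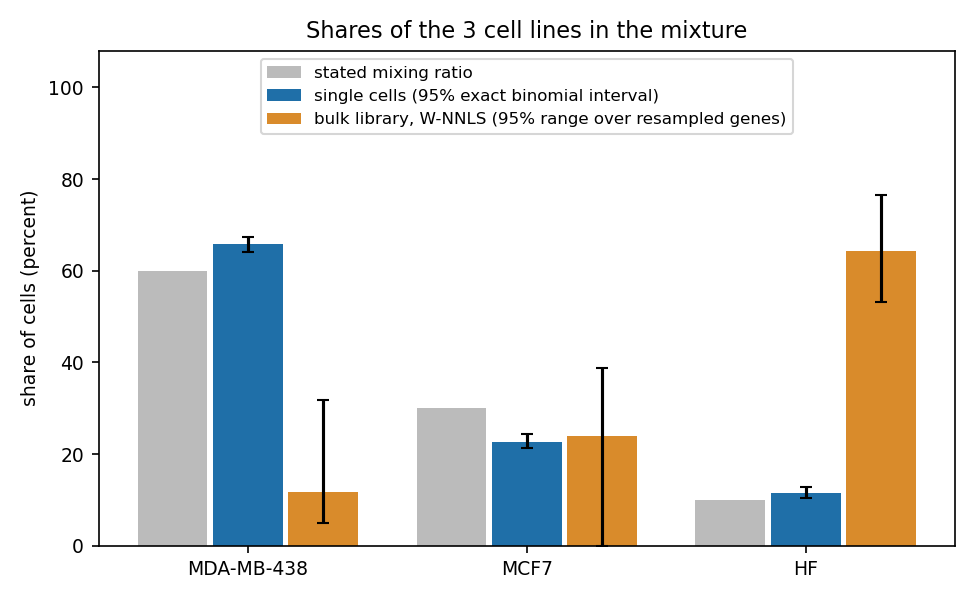
Percent of the 3 cell lines in the mixture as stated, as counted in single cells with exact 95% intervals, and as estimated in bulk by W-NNLS with gene resampling intervals. HF was 11.5% of the single cells and 64.4% in the bulk estimate.

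Set against bulk from the same mixture, ribosomal protein genes held a far larger share of counts in the summed single cells. Fibroblast matrix genes held a far smaller share. The ratios were not corrected for gene length, and the random lists were matched on expression alone. They are thus not ratios of transcript numbers, and gene length was not tested in human genes. Of 81 ribosomal protein genes, 80 were higher in the single cells, with a median log2 ratio of 2.60 (percentile 100 among random lists). RPS12 stood at 4.34, RPS18 at 3.92 and RPL13 at 3.56. All 10 HF genes that entered were lower in the single cells, with a median of −3.22 (percentile 0.04), among them the fibronectin gene FN1 at −4.54, COL1A1 at −3.86 and COL1A2 at −3.19. The median of all 5360 genes that entered was −1.71. The other lists lay within the central 95% of random lists, with medians of 1.22 for MDA-MB-438 (percentile 87.5; S100A9 at 2.25, KRT5 at −2.23, EGFR at −3.08), −2.01 for MCF7 (9.65; TFF1 at 1.36, XBP1 at −1.25, GATA3 at −1.48), −0.34 for proliferation (70.1; MKI67 at −2.94) and −0.24 for mitochondrially encoded genes (8.70). Only 1 histone gene entered, HIST1H4C, a replication-dependent histone whose mRNA carries no poly(A) tail, and it had the highest ratio at 13.26 with 60501 UMIs against 10 bulk counts. With genes from 10 CPM, 17 histone genes entered, 11 of them higher in the single cells, with a median of 2.07 (percentile 100), so that 3 of 7 lists lay outside in place of 2 of 6. The next highest ratios were NACA2 at 9.20, ATP5EP2 at 7.02, the nuclear RNA MALAT1 at 6.31, NHSL2 at 5.99 and TMEM160 at 5.89. The lowest ratios were in read-through genes and near-identical copies, whose reads cannot be placed with certainty. NME1-NME2 had 2 UMIs against 35540 bulk counts, AKAP2 had 3 against 12111, 3 genes of the CH507 group had 1 to 3, and HNRNPUL2-BSCL2 had 0 UMIs, a log2 ratio of −11.72 or lower with 3 UMIs as the floor. Spearman's rho across 32957 genes was 0.911. These values compare 2 libraries and have no replicate error.

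In mouse 3, dissociated gland cells were mostly stromal. Fibroblasts were 1922 of 4292 cells, 44.8% (43.3 to 46.3), and endothelial cells 895 cells, 20.9% (19.6 to 22.1), of which 26 carried lymphatic genes. Luminal cells were 13.7% (12.7 to 14.7), split into 418 secretory cells led by Wfdc18, Ltf and Csn3 and 169 hormone-sensing cells led by Ptn, Prlr and Pgr. Basal/myoepithelial cells were 11.1% (10.2 to 12.1), pericytes 3.66% (3.12 to 4.26), immune cells 1.93% (1.54 to 2.39) and Schwann cells 0.676% (0.453 to 0.969). A further 142 cells, 3.31% (2.79 to 3.89), were left unnamed. No cluster of adipocytes was found. When each cell was called by its marker UMIs alone, luminal cells were 27.5% and basal cells 7.32%.

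Among the 6 largest clusters of these cells, some of the stress transcripts that were high in the suspension were spread far more unevenly than others. In the 6 largest clusters, immediate early genes summed to 2525 to 3709.6 CPM and heat shock genes to 6998 to 12143 CPM, while NF-kB and chemokine genes summed to 40801 CPM in the largest fibroblast cluster, 6789 in the largest endothelial cluster and 1754 in luminal secretory cells. The 5 genes that follow were chosen after their values were seen. Mmp3 stood at 6804 CPM in fibroblasts (counting interval 6759 to 6849), 246 in endothelial cells and 169 in luminal cells. Saa3 stood at 13921 CPM in fibroblasts and 556 in luminal cells. Cxcl5 stood at 3913 CPM in fibroblasts and 4385 in pericytes, against 65.4 in luminal cells. Hmox1 stood at 3455 CPM in endothelial cells, 1208 in fibroblasts and 162 in luminal cells. Ltf stood at 2502 CPM in luminal cells and 8.07 in fibroblasts. Levels in the low classes were not separated from free RNA: Mmp3 UMIs were seen in 75.2% of fibroblasts and also in 43.3% of luminal cells, at median depths of 6341.5 and 8450.0 UMIs. These values come from 1 mouse.

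In the mouse bulk libraries, W-NNLS on the 6 classes gave lower immune and higher fibroblast shares in the suspension. Immune cells went from 21.2% ± 1.06 in fresh-frozen gland to 2.51% ± 0.668 in the suspension (SD, n = 2), a difference of −18.7 points. The immune profile came from 1 cluster of 83 cells whose best marker list was that of macrophages. No cluster had the T and NK cell list or the B cell list as its best. Lymphocytes thus had no class of their own, and the immune share is not a share of all immune cells. Fibroblasts went from 0% in both fresh-frozen libraries to 17.5% ± 2.66, endothelial cells from 48.1% ± 0.483 to 57.1% ± 2.04, and luminal cells from 3.18% ± 0.163 to 8.02% ± 0.637. Basal cells went from 16.5% ± 1.03 to 7.19% ± 2.03 and pericytes from 11.1% ± 0.676 to 7.67% ± 2.61, with a difference of −5.74 points in mouse 3 and −1.09 in mouse 4. Within mouse 3 and mouse 4 the immune difference was −18.4 and −19.0 points, and the fibroblast difference 19.4 and 15.6 points. The exact permutation p was 0.333 for each class, the smallest that 2 against 2 libraries allow. The estimates moved with the method: without weights, endothelial cells took at least 93.4% of each fresh-frozen library and immune cells 0% of all libraries, and the basal difference was 44.5 points. With the 50 leading genes of each class the basal difference was 2.01 points, and fibroblasts went from 49.0% to 53.2%, a difference of 4.24 points. Median ratios of the leading genes put fibroblasts at 45.7% in fresh-frozen gland and 42.8% in the suspension, a reversed difference of −2.94 points. The endothelial difference of 9.06 points was 2.71 with profiles scaled to CPM and 1.99 with the leading genes. Adipocytes were not among the classes because clustering found none in the single-cell reference, where calling by marker UMIs gave 5 cells. Adipocyte RNA thus had no class of its own, and the fresh-frozen shares are not shares of all gland cells. The correlation across genes between fitted and measured log2 levels was 0.759 and 0.769 in fresh-frozen 3 and 4. It was 0.854 in both suspensions. The 0% for fibroblasts in fresh-frozen gland cannot be read as their absence, because fibroblast genes such as Dcn were measured there. Leading genes and median ratios gave 49.0% and 45.7% for the same libraries. The main fibroblast difference rests on that fitted 0%. Fibroblasts at 19.4% in bulk suspension 3, or 17.7% to 55.0% over the alternatives, compare with 44.8% of the counted cells of mouse 3.

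**Figure D3:**
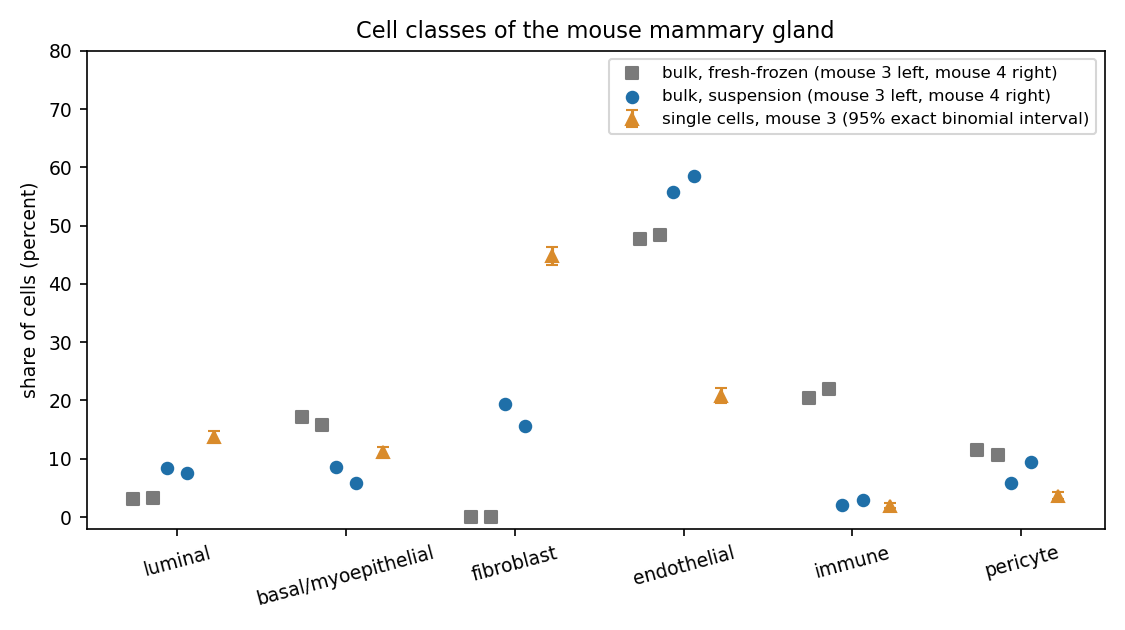
Percent of 6 cell classes by W-NNLS in the 2 fresh-frozen and 2 suspension bulk libraries (a point for each library), beside the share of single cells of mouse 3 with exact 95% intervals. The immune class, fitted from 1 cluster named by macrophage genes, averaged 21.2% in fresh-frozen gland and 2.51% in the suspension.

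The summed single cells of mouse 3 were last set against bulk of the same mouse's suspension, which gives the difference between the assays. In the NF-kB and chemokine list, 9 of 11 genes were higher in the single cells, among them Saa3 at 2.33 and Cxcl1 at 1.46 on the log2 scale, with a median of 1.14 (percentile 81.7). In the oxidative stress and metallothionein list, 6 of 9 genes were lower, among them Hmox1 at −1.02, while Mt1 stood at 3.40 and Mt2 at 2.52 (median −1.23, percentile 13.4). Relative to the median gene, 6 of these 9 were higher, Hmox1 among them, with a median of 0.07. Hspa1b (−5.98), Pgk1 (−4.46), Col3a1 (−2.41) and Mmp14 (−2.11) were lower in the single cells. The ratio of Hspa1b is uncertain because Hspa1a is a nearly identical copy. None of the 16 lists with enough genes had a median outside the central 95% of random lists. The nearest were lipid synthesis and lipolysis at −2.21 (percentile 2.59) and the fibroblast list at −1.49 (percentile 4.89). With genes from 10 CPM, 22 lists could be tested and 2 lay outside. The mast cell protease Mcpt4 had 0 UMIs against 1557 bulk counts, a log2 ratio of −8.60 or lower with 3 UMIs as the floor, and Cma1 had 5 UMIs and a ratio of −7.99. The haemoglobin gene Hbb-bs was higher in the single cells, at 2.82. The highest ratios were in ribosomal pseudogenes and unnamed genes, such as Rpl13-ps3 at 10.26 and Rps18-ps3 at 9.57, which are near-identical copies of other genes and so uncertain. Among the lowest were Gm26825 (−10.19), Gm28062 with 1 UMI against 11712 bulk counts, Galnt2 with 3 against 4474 and Cpne1 with 3 against 4195. The median of all 5177 genes was −1.30, and Spearman's rho across 27826 genes was 0.932.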

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

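The tests of the gene share at shared barcodes and of gene length were set before their results were seen, and the tests of the number of shared barcodes, pseudogenes, lymph node stroma genes, granulocyte genes and macrophage genes were chosen after the result was seen. No biological explanation was tested for the mouse 4 matrix or for the assay differences.

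The mouse 4 single-cell matrix was too thin for the filter, with 38281 UMIs in all, and its genes are described here only as sums. Of the 17 cell type lists, 11 were above the floor of 3 UMIs. The luminal secretory list had 156 UMIs, the basal/myoepithelial list 75, the fibroblast list 53, the pan-luminal list 51 and the luminal hormone-sensing list 25. The macrophage list had 16 UMIs, the skeletal muscle list 11, the adipocyte list 9, the endothelial list 8, the pericyte list 8 and the erythroid list 7. Luminal secretory genes had the largest sum in both matrices, with 0.408% of UMIs in mouse 4 and 0.664% in mouse 3, while fibroblast genes held 0.138% and 0.485%. Other lists held more in mouse 4, such as basal/myoepithelial genes with 0.196% against 0.0671% and macrophage genes with 0.0418% against 0.00978%. Of the 156 luminal secretory UMIs, 101 lay at barcodes not shared with mouse 3.

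The matrices of mouse 3 and mouse 4 shared 634 barcodes, 48.3 times the 13.1 expected from the 14 and 8 that they shared with the human mixture, which argues against barcodes drawn independently in the 2 libraries. At the shared barcodes, 80.9% of the 5921 UMIs of mouse 4 lay in genes that the same barcode of mouse 3 held, against 69.4% to 73.2% in 100 permuted pairings and the 90% set in advance for reads of mouse 3. Pseudogenes held 4.73% of these UMIs, 5.61 times the share in mouse 3, where thinning to as many UMIs gave 0.540% to 1.20%, which argues against reads of mouse 3 alone. The gene share lay above every permuted pairing, which argues against a source unrelated to the same barcode of mouse 3. It also lay between the 2 outcomes set in advance. Reads of mouse 3 mixed with other material and another source tied to the same barcodes thus cannot be told apart. At the other barcodes of mouse 4, pseudogenes held 7.30% of UMIs against 0.843% in mouse 3, a ratio of 8.66 that argues against a thin sample of the same kind of cells as in mouse 3, and thinned mouse 3 gave 0.732% to 0.964%.

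Genes of T and B cells were far lower in the suspension than in fresh-frozen gland, and 3 candidate explanations were tested. The 8 lymph node genes all fell (median log2 fold change −5.06; Sell 180 to 7.75 CPM), but 6 of them, Sell, Cr2, Fcer2a, Cxcr5, Ltb and Ccr7, are made by lymphocytes themselves, and Ccr7 is also in the dendritic cell list, while the stroma genes Ccl19 (99.3 to 3.24 CPM) and Cxcl13 (86.1 to 27.2 CPM), with −4.93 and −1.65 and a median of −3.29, are too few to decide on lymph node tissue. Blood was not decided by the granulocyte genes (median 2.49), because S100a8 and S100a9 stood at 0.321 and 0.399 CPM in fresh-frozen gland and 907 S100a8 UMIs of mouse 3 lay in luminal cells, which leaves Csf3r, at 2.73 and 15.4 CPM; all 3 are also in the neutrophil and mast cell list. An equal loss of all immune cells is argued against by the macrophage list, whose median lay 2.96 above that of the T and NK cell list. Lymph node tissue, blood and a selective loss of lymphocytes in the dissociation stay open, the last untested.

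Genes differed between the single-cell sum and the suspension bulk of mouse 3 in relation to their length. Spearman's rho between the log2 ratio and exonic length was −0.509 over 5058 genes. The median ratio was 0.61 in the shortest 1267 genes and −1.31, −1.82 and −1.82 in the groups of longer genes, in order of length. Most of the fall thus lay between the shortest group and the next, and the longest group hardly differed from the one before it. Gene length, which full-length bulk libraries count and 3 prime libraries do not, may account for part of the difference. Genes are not independent replicates, and other gene features that go with length were not separated from it.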

How the results depend on the processing

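Upper-quartile and total-count scaling, the settings without ribosomal protein and mitochondrial genes, other weight constants, bulk counts per kb, median ratios, Schwann and unnamed cells in the reference, the genes of cell type lists alone, leaving out stress and adipocyte list genes and removal of cells with genes of 2 lines were chosen after the result was seen. Where values moved below, the cause was not tested.

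Between fresh-frozen gland and suspension, the count of changed genes was 13266 and ranged from 11203 to 13860 over 12 alternatives, and called genes shared with the alternatives kept their sign. With 1 library left out the lowest and highest counts were 11203 and 13050, and such fits assume that a lone library varies like the other group. Of the lists, 20 passed camera with the preset correlation and 0 with an estimated correlation, and 19 to 23 passed with 1 library left out. The dendritic cell list was lost without fresh-frozen 4 (adjusted p = 0.0615). Without suspension 4, pericyte (0.0178), proliferation (0.0178) and neutrophil and mast cell lists (0.0219) passed. The last also passed without suspension 3 (0.0413) or fresh-frozen 3 (0.0339) and with upper-quartile or total-count scaling (both 0.0482), and proliferation without suspension 3 (0.0441). Fry, which asks whether a list changed at all and not whether it changed more than other genes, passed 23 lists. Its adjusted p was 0.0684 for hypoxia and 0.0307, 0.0111, 0.0111 and 0.0150 for pericyte, Schwann cell, proliferation and neutrophil and mast cell lists, which are not gains or losses of the camera calls. Lyve1 was lost without the count filter and without fresh-frozen 3, Mfge8 without suspension 4 or fresh-frozen 3, Acta2 without fresh-frozen 4, Rgs5 without either fresh-frozen library, and Mbp without suspension 3 or fresh-frozen 3. Ldha was gained without suspension 3, and Col1a2 and Acta1 without fresh-frozen 3 and with DESeq2. No named gene or list that passed in the main fit or in the alternative changed direction between them. Sign changes where neither fit passed were not counted.

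With mouse as a replicate block 13334 genes changed and 21 lists passed. The block changed the calls of Lyve1, Col1a2, Cpa3, Acta1 and the neutrophil and mast cell list as given in the report, and no other named call.

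Cells of mouse 3 called by marker share gave 27.5% luminal, 15.5% endothelial, 7.32% basal, 2.87% pericyte, 1.35% immune and 0.419% Schwann cells, with 5 adipocyte, 14 erythroid and 2 skeletal muscle cells. At a resolution of 1.5 Schwann cells were 1.19%. Single-cell shares of the 3 human lines stayed within their intervals in all settings, but the HF share was 10.6% or 10.7% in 5 of them, with intervals that held the stated 10%. Unnamed human cells numbered 27 at a resolution of 1.5, 27 without a cell filter and 29 with doublets kept. A doubled UMI minimum moved nothing there, since it removed no cell.

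In the bulk mixture, unweighted least squares gave MDA-MB-438 72.1% and HF 0%. The 50 leading genes gave MCF7 55.6% and HF 19.8%, and profiles scaled to CPM gave HF 50.4%. Without ribosomal protein and mitochondrial genes the shares were 2.02% MDA-MB-438, 49.7% MCF7 and 48.3% HF. A weight constant of 1e-08 gave MCF7 53.0% and HF 38.4%, 1e-06 gave 53.9% and 40.2%, and 1e-02 gave MDA-MB-438 90.3% and HF 4.70%. Median ratios gave MCF7 49.6% and HF 21.99%.

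In mouse bulk, differences are suspension minus fresh-frozen in points. Unweighted least squares reversed basal (44.5) and endothelial (−94.9) and gave luminal 9.87, fibroblast 40.5, immune 0 and pericyte 0. The leading genes reversed basal (2.01) and gave luminal 9.67, fibroblast 4.24, endothelial 1.99 and immune −14.4. Profiles scaled to CPM gave luminal 7.54, endothelial 2.71 and immune −15.8. Bulk counts per kb of exon gave basal −13.4, fibroblast 32.5 and immune −28.4 and reversed pericyte (1.17). Schwann and unnamed cells in the reference gave basal −6.23 and immune −17.4 and reversed pericyte (1.44). Cell type lists alone reversed basal (6.29) and gave fibroblast 40.6, immune −51.1 and pericyte −12.4. Leaving out stress and adipocyte list genes gave pericyte −6.27. Median ratios reversed basal (6.23), fibroblast (−2.94) and endothelial (−0.29) and gave luminal 7.80, immune −10.7 and pericyte −0.05. The mean luminal difference kept its sign in these settings, but with counts per kb it was 0.261 points, with 0.874 in mouse 3 and −0.352 in mouse 4 (exact p = 0.667). A reference from 1 mouse alone was not run apart from the main one, which already is mouse 3.

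In the human assay comparison 2 lists lay outside the random range, and 3 from 10 CPM. In the mouse assay comparison, the lists outside the random range were 0, 2 from 10 CPM and 1 with all deposited barcodes. Centring on the median gene cannot change a percentile.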

Other observations

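The groups of cells and genes described here were all noticed after the result was seen, and no explanation was tested for them.

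MDA-MB-438 cells of the mixture fell into 5 clusters, of which 4 are described by their leading genes; no list of hypoxia genes was tested in human cells. A cluster of 187 cells, 6.23% of all cells, was led by CA9, a carbonic anhydrase, with EGLN3, DDIT4, PGK1 and NDRG1. A cluster of 255 cells (8.49%) was led by the histone HIST1H4C. Clusters of 486 cells (16.2%) and 341 cells (11.4%) carried mitotic genes such as CDC20 and CCNB1, and their summed proliferation genes stood at 3018 and 3148 CPM, against 981 CPM in the largest MDA-MB-438 cluster. MCF7 stood at 659 CPM and HF at 1137 CPM for the same genes.

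Among mouse 3 fibroblasts, 219 cells (5.10% of all cells) were led by genes of the unfolded protein response, with Herpud1, Sdf2l1, Hspa5 and Ddit3. That list summed to 10935 CPM in them, against 1273 to 3173 CPM in the other fibroblast clusters. NF-kB and chemokine genes summed to 62744 CPM in a cluster of 216 cells led by Apod and Saa3, to 40801 CPM in 850 cells led by Serpinb2 and Mmp3, and to 29579.8 CPM in 602 cells led by Pi16. The 142 unnamed cells expressed Gal, Myod1, a transcription factor of the muscle lineage, and Des, and their best marker list was that of fibroblasts with a score of 0.581. In 455 endothelial cells led by Gpihbp1, the haemoglobin genes Hbb-bs and Hba-a1 were among the leading genes.

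Between the mice, 7 genes differed in the bulk libraries once tissue state was accounted for, with adjusted p of 0.0387 to 0.0391 in edgeR's quasi-likelihood test. Mrgprg was higher in mouse 4 by 4.93 on the log2 scale and Gm21857 by 3.70. Saa2, an acute-phase protein, was higher by 1.52 and Pigr, a receptor that carries antibodies across epithelium, by 1.40. Saa2 had 7 and 2 counts in fresh-frozen 4 and 3, so its difference rests on the suspension pair. Mup9, Mup10 and Mup19, urinary protein genes, were lower in mouse 4, with −1.47, −1.24 and −1.86, and are uncertain because Mup genes are near-identical copies. In suspensions 4 and 3, Mup9 had 2 and 4 counts, Mup10 7 and 7, and Mup19 0 and 3. The Mup differences thus rest on the fresh-frozen pair. Litter, cage and cycle stage are not given in the sources used here.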
